A study of Mus musculus with 4 samples.

How the data were processed

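The series holds 4 mouse libraries, 2 of control and 2 of Rcor1 mutant erythroid progenitors, grouped by their titles. Per the labels, each library pools RNA of several fetal livers and the 2 libraries of a group are biological replicates; the control pools mix 2 genotypes in a proportion that is not given in the sources used here. Per the submitters' processing notes, FastQC, Bowtie and edgeR were used with the mm9 genome; no version is given there. The count columns named WT, with the numbers 1 and 2, were assigned to the control samples by number, as the only group besides the mutant; the authors' comparison column also says WT, and no label states the assignment outright. The authors deposited a table of whole-number counts per gene, taken to be raw because each library sums to a different total, and a table of their own comparison with log2 fold changes and p-values, per the file headers. How reads that map to several places were counted, and whether strand was used, is not given in the sources used here, so near-identical genes and overlapping genes on opposite strands are uncertain. The files hold no coordinates, and none are printed.

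The count table had 35939 gene rows. The 12 mitochondrial rows that held NA in every library were left out, which left 35927. Gene symbols were those of the files, matched to lists by symbol or by an older symbol written beside it in the list; 25 symbols had been turned into dates by a spreadsheet and were not eligible as named genes. Library totals ran from 15053229 to 26892375 counts. The leading gene of each library, Gnb2l1, took at most 0.602% of counts. Replicates were compared over 10006 genes with at least 100 counts in each group: chi-square per gene was 5.76 between controls and 3.67 between mutants, well above the value of about 1 that counting alone gives, so no library was treated as a duplicate.

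Counts were fitted with edgeR 4.0.16 in R 4.3.3 (limma 3.58.1): filterByExpr left 13140 genes, TMM factors ran from 0.952 to 1.05, and the quasi-likelihood test (estimateDisp, glmQLFit with robust, glmQLFTest) compared mutant with control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.00232, a coefficient of variation of 4.81%. Low spread between pooled libraries makes small changes pass, so sizes are printed beside calls. The standard error is the absolute log2 fold change over the square root of F. An exact permutation test of 2 against 2 libraries cannot go below p = 0.33, so shares of counts were given without a test. Intervals on shares are Wilson 95% intervals and cover counting error only. The interval for the ratio of a gene with 1 to 3 counts in a group comes from an exact binomial test.

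The 23 gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The lists had 401 entries, 397 in the table and 318 tested; Ahsp, Icam4, Cebpb and Hspa1a were not found by symbol. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 23 lists, and 13 passed. None passed with the correlation estimated from the data (smallest adjusted p = 0.17), and fry was run beside it. With an estimated correlation, camera takes its degrees of freedom from the libraries, so it has little power with so few. The cell cycle list had an estimated correlation of -0.0179, below the preset, yet its unadjusted camera p went from 6.4e-05 to 0.0459. A miss with an estimated correlation therefore does not show that a list was unchanged. Counts of members adjusted over the list alone equalled those over all genes for 18 of the 23 lists. Named genes were a fixed set of 24, the 10 largest rises and 10 largest falls among called genes with no overlap of groups, a mean of at least 10 CPM in the higher group and no clone name, up to 3 risers and 3 fallers of each list (where none passed, the member with the highest mean CPM), and all members of any count of 5 or fewer; some genes and gene families that these choices take in are not reported here.

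Alternatives were RLE and upper quartile scaling, TMM without the globin list, library totals alone (added after seeing the data), no filter beyond 1 count, CPM above 1 in 2 libraries, DESeq2 1.42.0, edgeR's exact test, limma-voom, glmQLFit without robust, an added 2-fold threshold, the replicate number as a block, and each library left out in turn, which leaves 1 group with a single library assumed to vary like the others. The fit was tested on simulated counts for the 13140 genes of the mutant against control comparison. In the simulation 200 genes were changed, about equally up and down. It recovered 46 of 67 genes changed 1.5-fold, 53 of 67 changed 2-fold and 64 of 66 changed 4-fold. None went in the wrong direction, and 5 unchanged genes were called. In the data 7558 genes were called, with more large rises than large falls. The simulation therefore does not give the recovery in these data and does not test the scaling.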

Results

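Gene expression was measured by mRNA sequencing in erythroid progenitors of the mouse fetal liver at embryonic day 13.5, the organ and stage at which definitive red cells are made. The cells had been sorted as positive for CD71, the transferrin receptor, and negative for TER119, a marker of later erythroid cells. The mutant embryos carried no wild-type copy of Rcor1, which encodes the CoREST scaffold protein that holds the demethylase Kdm1a and histone deacetylases together. The control group joined wild-type and heterozygous embryos. Each group had 2 libraries, and each library pooled RNA of several livers. The control libraries held 26892375 and 22817080 counts, and the mutant libraries 25186819 and 15053229. In the text below, a level is given as CPM (counts scaled by library total and TMM factor) with its SD over n = 2 libraries, and a change as the log2 fold change of mutant over control from edgeR's quasi-likelihood test with its standard error and Benjamini-Hochberg adjusted p.

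Rcor1 (ENSMUSG00000037896) had 4083 and 3807 counts in the control libraries and 2061 and 1240 in the mutant libraries. Its level was 167 ± 10.5 CPM in controls and 78.4 ± 0.723 CPM in mutants, a change of -1.09 ± 0.06 (adjusted p = 4.6e-11). The counts are per gene, so they do not show which exons the remaining mutant reads cover. Among the 15 genes of the CoREST complex and its partners, 5 rose, 6 fell and 4 did not pass. The risers were Phf21a (1.58), Gfi1b (1.43), Gfi1 (1.34), Rcor2 (0.96) and Zmym2 (0.35). Gfi1b, a transcriptional repressor that recruits the complex in erythroid cells, went from 509 ± 18.9 to 1369 ± 53.2 CPM (adjusted p = 7.56e-14). Rcor2, a paralog of Rcor1, went from 17.9 ± 0.619 to 34.8 ± 1.29 CPM, while the other paralog, Rcor3, fell by 0.53 from 5.78 ± 0.843 CPM. Kdm1a fell by 0.31, and Gse1 by 0.42. As a list these genes did not pass (camera adjusted p = 0.641, direction up), with a median of -0.19 and a mean of 0.16; under total count scaling the median was -0.05 with 4 falls, and without control replicate 1 it was -0.08. The calls of 2 scarce genes were not stable: without control replicate 1, without mutant replicate 1 and with DESeq2, Rcor3 had adjusted p = 0.148, 0.0777 and 0.137 and Gfi1 0.0783, 0.106 and 0.164, and Rcor3 had 0.0519 under total count scaling. Over scaling, filter, test and left-out libraries, their adjusted p ran from 0.00101 to 0.148 and from 0.00175 to 0.164.

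Among called genes with a mean of at least 10 CPM in the higher group and no clone name, the highest rises in the Rcor1 mutant cells were those of Csf2rb, which encodes the beta chain shared by the receptors for interleukin 3, interleukin 5 and GM-CSF, and Csf2rb2, which encodes the beta chain of the interleukin 3 receptor alone: Csf2rb went from 1.56 ± 1.17 to 460 ± 9.05 CPM (log2 fold change 8.14 ± 0.27, adjusted p = 2e-04) and Csf2rb2 from 0.30 ± 0.295 to 87.1 ± 2.49 CPM (8.08 ± 0.21, adjusted p = 3.4e-11). Next came the opioid precursor gene Pdyn (6.92), the lipid transfer gene Osbpl5 (6.90), Rpp25 (6.78), the actin-binding Ablim1 (6.27), the tyrosine kinase Tec (6.05), Mpzl2 (5.86), the G protein subunit Gng2 (5.76) and Appl2 (5.62). The steepest falls under the same limit were those of Mgll, the lipase that hydrolyses monoacylglycerols, from 90.2 ± 1.52 to 7.33 ± 0.161 CPM (-3.62), and of Butr1 (-3.51), Apol8 (-3.10), the acyl-CoA synthetase gene Acsl6 (-3.02), the creatine synthesis gene Gatm (-2.83), the connexin gene Gjb2 (-2.59), App (-2.57), Trim2 (-2.48), the chemokine receptor gene Darc (-2.46) and Nags (-2.43).

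Of 13140 genes tested, 7558 passed adjusted p 0.05, 3723 of them higher and 3835 lower in the mutant. The sides were unequal in size of change: 1532 genes rose at least 2-fold and 237 fell as much. In 7554 of the called genes the groups did not overlap; over all tested genes this held for 77.9%, where chance gives 33.3%. The split depended on scaling. With library totals alone in place of TMM, a choice made after seeing the data, the median log2 fold change of all genes moved from 0.01 to 0.15 and the split became 5112 higher and 2553 lower; upper quartile scaling gave 4423 and 3088. Changes below are relative to the TMM scale. Csf2rb and Csf2rb2 are near-identical copies, so the division of reads between them is uncertain. For 3 of the top genes the size rested on the control libraries, which differed: without control replicate 1 and without control replicate 2 the log2 fold change was 9.27 and 7.57 for Csf2rb, 9.80 and 7.39 for Csf2rb2, and 7.10 and 5.49 for Tec.

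**Figure D1:**
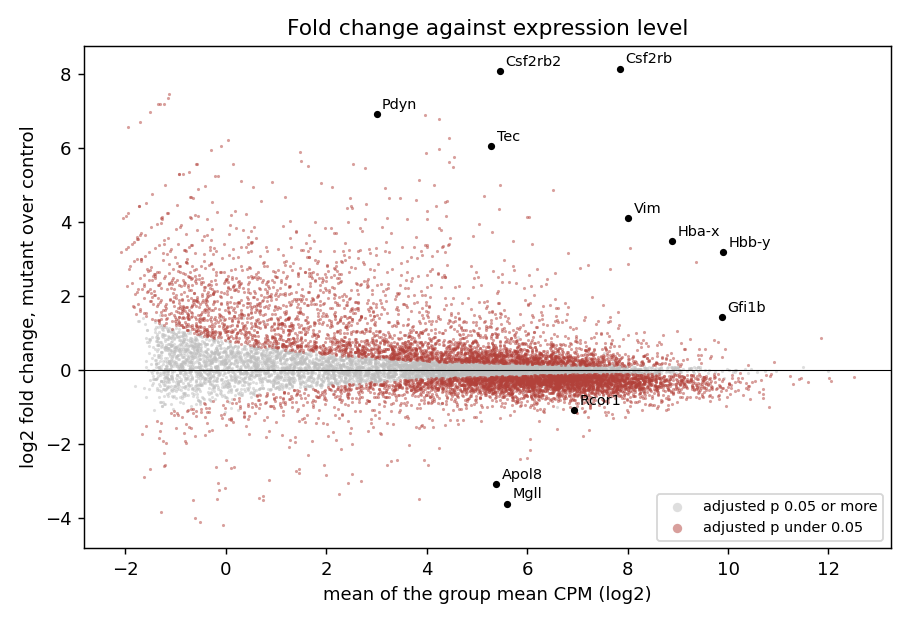
Each point is one of 13140 tested genes; the x axis is the mean of the group mean CPM (log2) and the y axis the log2 fold change of mutant over control. Red points have adjusted p under 0.05, and labelled genes such as Csf2rb (8.14) and Mgll (-3.62) mark the high and low ends among well-expressed genes.

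Most tested genes of stem and progenitor cells, of granulocytes and monocytes, and of megakaryocytes were higher in the mutant progenitors. Of 20 tested stem and progenitor genes, 16 rose and none fell, with a median of 1.81. The filter kept genes expressed in either group, so a gene scarce in controls, such as Flt3, was tested only because mutants expressed it. Counts of rises and medians of lists with such genes can therefore lean upward. The surface marker Cd34 went from 1.77 ± 0.368 to 30.3 ± 0.800 CPM (4.08), Flt3 changed by 3.93 and the ETS factor Fli1 by 3.32. The homeobox gene Meis1 went from 2.77 ± 0.431 to 13.4 ± 0.502 CPM (2.29) and Gata2, a factor of early progenitors, from 3.78 ± 0.679 to 13.3 ± 0.732 CPM (1.79). The 4 members that did not pass were Kit (0.06 ± 0.05), Etv6, Lyl1 and Hlf. Hoxa9 was too scarce to test, with 2 and 2 counts in controls and 7 and 6 in mutants, and Myb, a progenitor factor of another list, had 0.07 ± 0.05. Kit and Myb passed under upper quartile and total count scaling (0.13 and 0.19 for Kit, 0.15 and 0.21 for Myb), and their adjusted p over all scalings, filters, tests and left-out libraries ran from 0.00162 to 0.807 and from 0.000831 to 0.624. Flt3 rested on 2 and 4 control counts, and its value was 3.40 without control replicate 1 and 4.57 without control replicate 2. The list passed camera at adjusted p = 2.22e-09, but had adjusted p = 0.169 with an estimated correlation. Hepatoblast genes took 0.109% and 0.108% of counts in the control libraries and 0.161% and 0.16% in the mutant libraries.

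Of 28 granulocyte and monocyte genes, 23 rose, with a list median of 2.16. Sfpi1, which encodes the myeloid factor PU.1, went from 10.6 ± 2.54 to 82.7 ± 3.08 CPM (2.96), and Fcgr2b changed by 3.22 and Cd33 by 3.13. Cebpa changed by 0.82, and the granule genes Mpo and Prtn3 were among the risers. The neutrophil elastase gene Elane fell (-0.87, adjusted p = 0.00331), and 4 other granule genes, Ctsg (-0.53), Ngp, Ltf and Camp, did not pass; a count adjusted over the list alone put 2 genes, Elane and Ctsg, among the falls. Elane had adjusted p = 0.0769 with DESeq2, the highest of a range that began at 0.000404. Camera gave adjusted p = 3.35e-12, and adjusted p = 0.169 with an estimated correlation. Of 20 megakaryocyte and platelet genes, 18 rose, with a median of 2.20: Plek, a platelet signalling protein, went from 5.51 ± 0.320 to 73.3 ± 3.13 CPM (3.74), and Mmrn1 changed by 3.11. Vwf fell (-0.59, adjusted p = 1.69e-05) and Gp9 did not pass (0.23). This list had adjusted p = 5.37e-16, and adjusted p = 0.169 with an estimated correlation. Cd33 rested on 6 and 1 control counts and moved to 4.69 without control replicate 1 and 2.46 without control replicate 2. Mesenchymal genes took 0.00112% and 0.00118% of counts in the control libraries and 0.00352% and 0.00323% in the mutant libraries.

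Of 16 myeloid cytokine receptor genes, 14 rose. Beside the beta chains, Il5ra, the specific chain of the interleukin 5 receptor, had 2 counts over both controls and 98 over both mutants, a ratio of 55.0 with a 95% counting interval from 14.8 to 461. Its fitted log2 fold change of 5.58 became 8.60 without control replicate 1 and 4.75 without control replicate 2. The interferon gamma receptor gene Ifngr1 fell (-0.95), and Csf2ra, the specific chain of the GM-CSF receptor, did not pass (-0.12). The list median was 1.25, the camera adjusted p = 4.83e-12, and adjusted p = 0.169 with an estimated correlation.

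**Figure D2:**
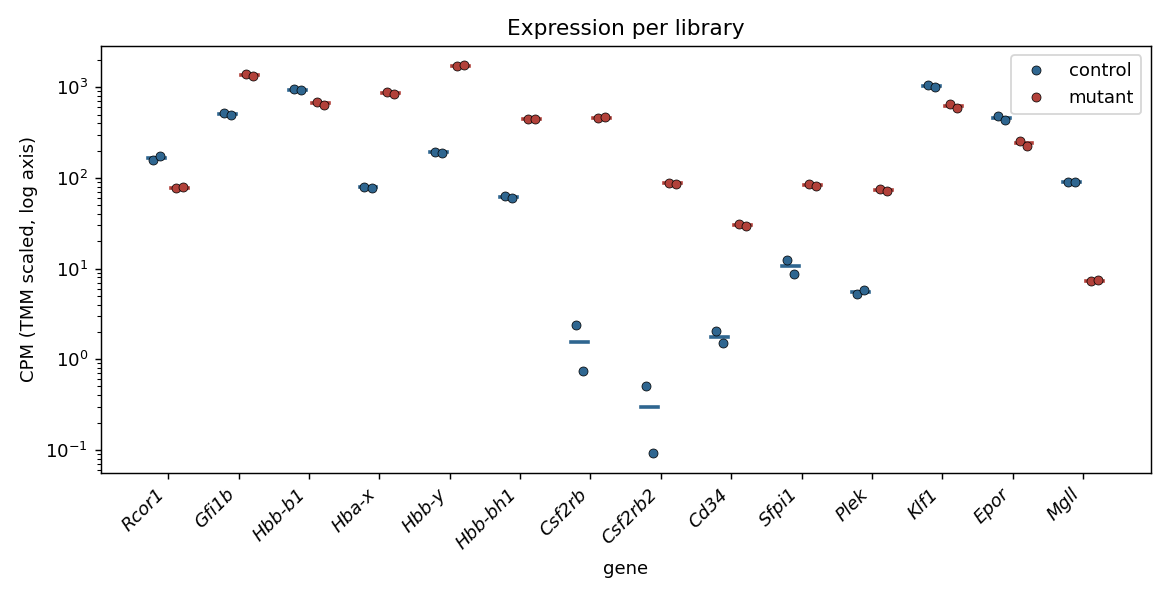
TMM-scaled CPM on a log axis for 14 genes (x axis), with 1 point per library, 2 control libraries in blue and 2 mutant libraries in red, and a bar at each group mean. Csf2rb stood at 460 CPM in mutants against 1.56 in controls, and the control points of Csf2rb and Csf2rb2 lay apart.

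Embryonic globin transcripts rose 9.04-fold (Hbb-y), 11.1-fold (Hba-x) and 7.33-fold (Hbb-bh1) in the mutant, while adult beta globin transcripts fell. Hbb-y went from 191 ± 3.44 to 1732 ± 24.7 CPM (3.18 ± 0.04), Hba-x from 78.7 ± 1.84 to 871 ± 27.7 CPM (3.47 ± 0.05) and Hbb-bh1 from 61.7 ± 3.15 to 452 ± 0.341 CPM (2.87 ± 0.05). The adult genes Hbb-b1 (-0.50) and Hbb-b2 (-0.69) fell, from 944 ± 7.74 and 990 ± 26.6 CPM. Hba-a1 (-0.24) and Hba-a2 (-0.19) did not pass. The adult pairs are near-identical copies whose counts are uncertain if shared reads were discarded. Hba-a1 had only 6.8 ± 1.7 CPM in controls and 5.8 ± 0.3 CPM in mutants, far below the adult beta genes. Adult alpha reads may thus be largely missing. The calls of Hba-a1 and Hba-a2, and the globin shares and list median below, do not show the level of adult alpha globin. Hepatoblast genes moved in the same direction by less, from 0.108% to 0.16% of counts. The 7 globins took 0.219% and 0.214% of counts in controls and 0.461% and 0.449% in mutants. As a list their median was -0.19 and their mean 1.13, and camera, which weighs the size of the changes, gave an upward adjusted p = 5.62e-15, with adjusted p = 0.169 with an estimated correlation and 0.0573 without control replicate 1, where the median was 0.05. Over total count scaling, the stricter filter and left-out libraries the adjusted p ran from 1.92e-16 to 0.0573. Hba-a1 passed without control replicate 2 (-0.48, adjusted p = 0.00931) and had up to 0.847 elsewhere.

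Erythroid genes were mostly lower, by modest amounts. Of 20 erythroid transcription factors and Epo signalling genes, 13 fell and 5 rose. Klf1, the activator of adult beta globin, went from 1030 ± 41.5 to 622 ± 52.3 CPM (-0.73), Gata1 from 536 ± 2.70 to 367 ± 3.44 CPM (-0.55) and the erythropoietin receptor gene Epor from 458 ± 38.1 to 241 ± 22.1 CPM (-0.92). Sox6 (-1.11), a repressor of embryonic globin genes, and Zbtb7a (-1.01) fell the furthest. The risers were Gfi1b, Cish (1.07), Bcl2l1 (0.91), Jak2 (0.49) and Nfe2 (0.28); Myb and Cbfa2t3 did not pass. The list missed the threshold (camera adjusted p = 0.11), and reached 0.0233, 0.0218 and 0.0411 without control replicate 1, without control replicate 2 and without mutant replicate 1, against 0.0978 without mutant replicate 2 and 0.26 under total count scaling, where the median moved from -0.29 to -0.15.

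Of 18 genes of haem synthesis and iron handling, 15 fell and 1 rose, with a median of -0.52. Uros, an enzyme of the haem pathway, fell by 1.28, the mitochondrial glycine carrier gene Slc25a38 by 0.99 and the ferrireductase gene Steap3 by 0.92. Tfrc, which encodes the sorting marker CD71, went from 1248 ± 160 to 882 ± 36.4 CPM (-0.50, adjusted p = 0.00794), and had adjusted p = 0.0702 without mutant replicate 1 and 0.0677 without mutant replicate 2, in a range that began at 3.61e-29. The ferritin gene Fth1 rose (0.21), and Ftl1 was among the 2 that did not pass. The list had adjusted p = 8.01e-09, and adjusted p = 0.242 with an estimated correlation; 12 genes fell under total count scaling. Of 24 red cell membrane and late erythroid genes, 19 fell and 4 rose, with a median of -0.41. Gypc (-1.54), Tmcc2 (-1.13) and Rhd (-1.10) were among the falls. The risers were Bpgm (0.98), the mitophagy receptor gene Bnip3l (0.70), Spna1 (0.33) and the glucose transporter gene Slc2a1 (0.31). This list had adjusted p = 6.23e-08, and adjusted p = 0.169 with an estimated correlation; under total count scaling 16 genes fell and 5 rose, and the median was -0.28.

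Of 28 cell cycle genes, 19 fell and 4 rose, with a median of -0.28; a count adjusted over the list alone gave 20 falls, with Ccnb2 (-0.10) added. Under total count scaling the cell cycle median was -0.14, with 15 falls and 5 rises. Cyclin E1 (Ccne1, -1.06), the replication helicase gene Mcm2 (-0.80) and Cdc20 (-0.75) fell the furthest, while Ccnd2 (0.72), Bub1 (0.41), Mki67 (0.33) and Top2a (0.18) rose. The list had adjusted p = 0.000184, and adjusted p = 0.169 with an estimated correlation. Of 15 p53 target genes, 10 rose: the cell cycle inhibitor gene Cdkn1a went from 5.26 ± 0.364 to 37.3 ± 0.892 CPM (2.83), Pmaip1 changed by 2.40 and Eda2r by 2.19. Sesn2 (-0.64) and Aen (-0.19) fell, and Bax, Ei24 and Tnfrsf10b did not pass; Aen had adjusted p = 0.0552 without mutant replicate 1, 0.0571 under upper quartile scaling and 0.354 under total count scaling, in a range that began at 8.93e-05. Camera gave adjusted p = 0.0111, and adjusted p = 0.325 with an estimated correlation. In the Bcl2 family, 4 genes rose (Bnip3, 1.95, with Bcl2l1, Bnip3l and Bmf), 4 fell (Bcl2l11, -0.61, Bid, -0.32, Mcl1, -0.23, and Bad) and 3 did not pass (Bax, Bak1 and Bcl2). The family had a median of -0.04, which became 0.10 under total count scaling, -0.01 with CPM above 1 in 2 libraries, and -0.005, -0.19, -0.12 and -0.10 when control replicates 1 and 2 and mutant replicates 1 and 2 were left out in turn, a mean of 0.20 and camera adjusted p = 0.446, direction up; Mcl1 had adjusted p = 0.13 under total count scaling, in a range that began at 3.99e-07. Of 11 immediate early and heat shock genes, 8 fell, led by Fos (-1.28), Btg2 (-0.86) and Junb (-0.57), and 3 did not pass (Jun, Zfp36 and Hspa1b); adjusted over the list alone, 1 rise was added, that of Zfp36 (0.47). This list had adjusted p = 0.0339, adjusted p = 0.307 with an estimated correlation, and 0.0515 without mutant replicate 1, in a range that began at 0.0202. Fos rested on 21 and 15 control counts and lost its call without control replicate 1 (adjusted p = 0.178), without control replicate 2 (0.0509) and without mutant replicate 1 (0.306), and with DESeq2 (0.295), in a range that began at 0.0242.

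**Figure D3:**
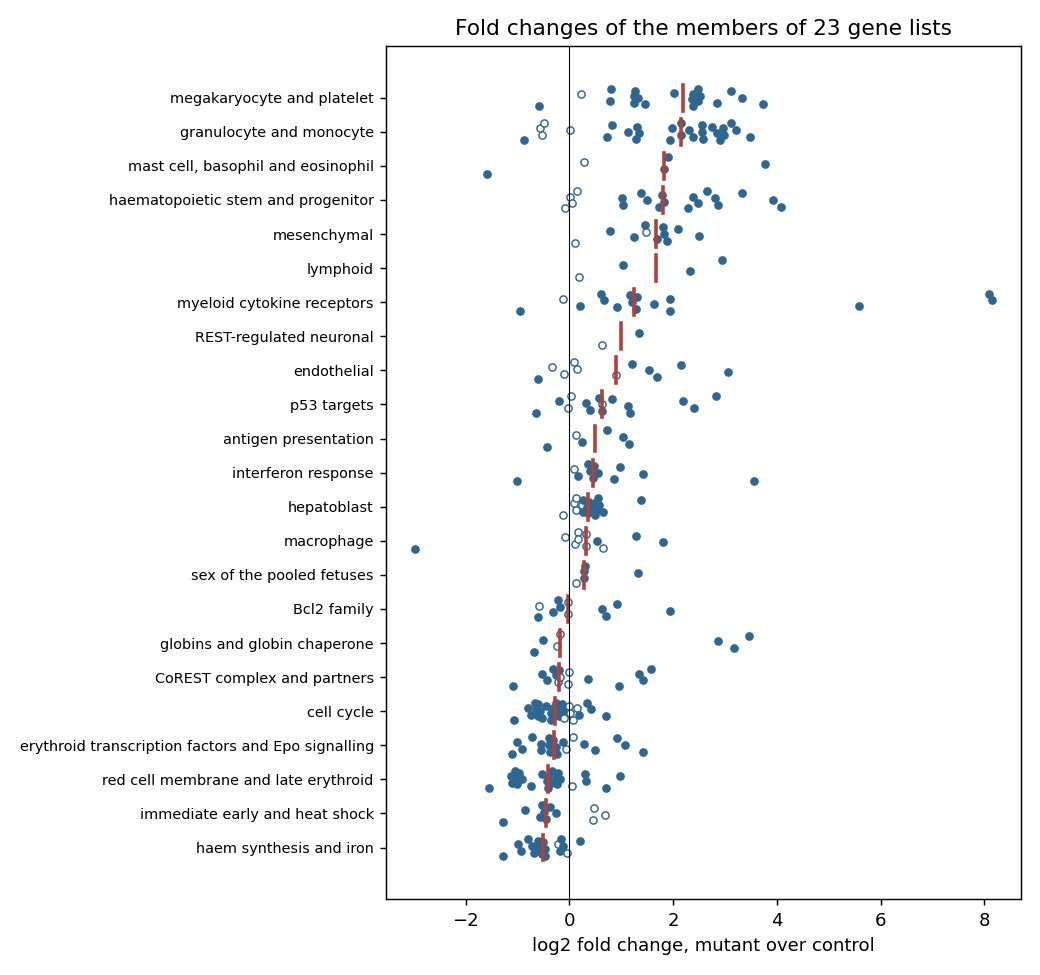
Log2 fold change of mutant over control (x axis) for the tested members of 23 gene lists (y axis), filled where adjusted p was under 0.05, with the list median as a red bar. Medians ran from -0.52 for haem synthesis and iron to 2.20 for megakaryocyte and platelet genes.

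Genes listed as markers of cells outside the sorted population were scarce and moved unevenly. The counts do not show which cells their transcripts came from, and Csf1r was also in the granulocyte and monocyte list. Hepatoblast genes took 0.109% and 0.108% of counts in controls (Wilson 95% intervals 0.107 to 0.11 and 0.107 to 0.109) and 0.161% and 0.16% in mutants (0.159 to 0.162 and 0.158 to 0.162); 13 of 18 rose, among them Krt18 (1.38), Hnf4a (0.65) and Trf (0.57), none fell, and camera gave adjusted p = 0.0312, with adjusted p = 0.304 with an estimated correlation. Of the mesenchymal genes, 9 of 11 rose, led by Lum (2.50), Postn (2.10) and Pdgfra (1.89), and Des and Acta2 did not pass (adjusted p = 0.0206, and adjusted p = 0.325 with an estimated correlation). Endothelial genes took 0.0184% and 0.0182% of counts in controls and 0.0204% and 0.0201% in mutants: Tek (3.05), Pecam1 (2.15), Esam, Tie1 and Kdr rose, Eng fell (-0.60) and 5 did not pass (Cdh5, Egfl7, Lyve1, Ramp2 and Stab2), with adjusted p = 0.11. Macrophage genes took 0.00411% and 0.00383% in controls and 0.00966% and 0.0102% in mutants, where Lgmn alone gave 1716 of 2432 and 1100 of 1529 counts: Lgmn (1.81), Csf1r (1.28) and Emr1 (0.54) rose, Marco fell (-2.97), and 7 did not pass, C1qa, C1qb and C1qc among them (adjusted p = 0.337). Emr1 passed narrowly (adjusted p = 0.046) and had 0.106, 0.166, 0.077 and 0.147 when control replicates 1 and 2 and mutant replicates 1 and 2 were left out in turn, and 0.359 with DESeq2; adjusted over the list alone 2 genes rose, Lgmn and Csf1r. Pdgfra had adjusted p = 0.0561 without control replicate 2 and 0.134 with DESeq2, in a range that began at 0.00176, and Postn 0.0519 with DESeq2, in a range that began at 5.78e-05.

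Only 5 of 14 mast cell, basophil and eosinophil genes were expressed enough to test. Cpa3 (3.76, on 4 and 5 control counts), Hdc (1.89) and Prg2 (1.83) rose, Il1rl1 fell (-1.59) and Epx did not pass (list adjusted p = 0.115). Of 19 lymphoid genes, 4 could be tested: Cd79b (2.95), Tcf7 (2.33) and Cd3g (1.03) rose and Lck did not pass (list adjusted p = 0.11). The risers had few control counts, 10 and 15 for Cd79b, 13 and 8 for Tcf7 and 10 and 12 for Cd3g. The call of Cd3g was not stable, with adjusted p = 0.305 with DESeq2. Its log2 fold change ran from 0.78 without control replicate 1 to 1.29 without mutant replicate 1. In antigen presentation, with 6 of 10 genes tested, Tap1 (1.14), H2-Ab1 (1.04), B2m (0.73) and H2-D1 (0.25) rose, Tapbp fell (-0.43) and H2-K1 did not pass (list adjusted p = 0.135). Of 12 interferon response genes, 10 rose, led by Oasl2 (3.57), Isg15 (1.42) and Ddx58 (0.98), Usp18 fell (-1.01) and Stat2 did not pass. That list had adjusted p = 0.0655, and 0.00837 without control replicate 1 and 0.0466 without mutant replicate 2; Isg15 had 0.0774 without control replicate 1 and 0.185 with DESeq2, in a range that began at 0.00405. Only 2 of 20 REST-regulated neuronal genes were expressed enough to test: Syp rose (1.34) and Tubb3 had 0.63 (adjusted p = 0.0795), which passed when adjusted over the list alone and under total count scaling (list adjusted p = 0.518). Syp had adjusted p = 0.0946 with DESeq2, the highest of a range that began at 0.000222.

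The pools could differ in the sex of their fetuses, so sex-linked genes were set side by side. Xist, the RNA of the inactive X chromosome, went from 97.2 ± 0.234 to 244 ± 0.630 CPM (1.33, adjusted p = 4.06e-13). The Y-linked genes Uty (0.31), Ddx3y (0.28) and Kdm5d (0.28) rose as well, and Eif2s3y had 0.13. The list had adjusted p = 0.0312, adjusted p = 0.325 with an estimated correlation and 0.0573 without control replicate 1, and over total count scaling, the stricter filter and left-out libraries it ran from 0.0216 to 0.0573. Uty had adjusted p = 0.257 without control replicate 1, 0.0843 without mutant replicate 1 and 0.0754 without mutant replicate 2, and Ddx3y 0.0972 without mutant replicate 2; with DESeq2 they had 0.187 and 0.0967, and the ranges began at 0.00131 and 0.000296.

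The authors' deposited table of mutant over control listed 13234 genes, of which 7321 had an adjusted p under 0.05, 4983 higher and 2338 lower. The refit called 6009 of these, all with the same sign; 1549 genes were called by the refit alone and 1312 by the authors' deposited table alone. The table gives 9 of its genes a change beyond 20 on the log2 scale; across the genes in both without any of those, the log2 fold changes had a Pearson r of 0.9999 (genes are not independent replicates). They differed by a median of 0.14, and for Rcor1 the authors' deposited table gave -0.96. Across 10855 genes above 1 CPM in every library, the table's values followed the log2 ratio of CPM over library totals with a slope of 0.999 and an intercept of 0.001.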

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

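All alternatives below were planned except total count scaling, which was chosen after seeing the data. The count of 7558 changed genes stayed within 5783 (DESeq2) and 8402 (replicate block) under the changes of scaling, filter, test and block, and no named gene changed sign past the threshold. Requiring a 2-fold change left 1769 genes, 1532 higher and 237 lower, by construction. Total count scaling lowered the count of falling genes to 2553, since it shifts every log2 fold change up by one amount. Leaving out 1 library gave 6234 to 7394 genes, 3034 to 3520 of them higher and 3200 to 3874 lower, with fewer libraries. Of 122 named genes, 69 kept their side of the threshold throughout; the 2-fold threshold ended 43 calls and DESeq2 12. Of the gene lists, 13 passed camera, 0 with an estimated correlation, 22 by fry's directional test and 23 by its mixed test, which ask other questions; without 1 library 13 to 14 passed. The hepatoblast share of mutant counts was 0.161% of a total without globins. The authors' adjusted p under 0.01 left 5529 shared genes.

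The titles share the numbers 1 and 2, but nothing says that these pair the libraries. Deviations from the group means correlated across genes at r = 0.12 (Spearman 0.15) between libraries of one number. With the replicate block, 8402 genes passed, 4135 higher and 4267 lower, and 14 lists; the globin list did not (adjusted p = 0.134), and the erythroid transcription factor (0.023) and interferon response (0.0119) lists did. With number in the fit, 434 genes differed between numbers. Of the 7558 called genes, 7556 had the same sign in both number pairs. In 7554 called genes the groups did not overlap, which gives the same sign under any pairing. The count therefore does not bear on whether the numbers pair the libraries. At this depth and spread, 46 of 67 simulated changes of 1.5-fold were recovered, with 200 genes changed in the simulation against 7558 called here. Recovery at the share of changes in these data, and by abundance, was not tested.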

Other observations

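All tests in this part were chosen after the results were seen. The genes and gene families of this paragraph and the next were picked after their values were seen, so their counts are descriptions and no test of a family is given. Vim, the intermediate filament of mesenchymal and blood cells, went from 28.5 ± 0.142 to 487 ± 5.64 CPM (log2 fold change 4.09 ± 0.05). The non-erythroid spectrin genes Spna2 (4.85 ± 0.09) and Spnb2 (2.82 ± 0.08) rose, while of the erythroid pair Spna1 rose by 0.33 and Spnb1 fell (-0.36). The actin regulators Coro1a (3.40), Tmsb4x (2.72) and Lcp1 (2.01) were higher. Integrins had 13 of 19 members higher and none lower (median 1.21), annexins 6 of 9 higher and 1 lower (1.69; Anxa5, 3.16, Anxa2, 2.73), coronins 3 of 6 higher (Coro2a, Coro1a and Coro2b) and 1 lower, and the 4 tested troponin genes, Tnni1, Tnni2, Tnni3 and Tnnt1, were all higher (2.71).

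Of 74 mitochondrial ribosomal protein genes, 45 fell and 4 rose (median -0.23), against 26 and 9 under total count scaling (-0.10). Of 37 proteasome genes, 21 fell and 2 rose (-0.16), against 14 and 3 (-0.03), and of 18 aminoacyl-tRNA synthetase genes, 14 fell and 0 rose (-0.22), against 9 and 2 (-0.09). Of 20 nuclear pore genes, 12 fell and 1 rose (-0.19), against 9 and 5 (-0.06). Of 77 cytosolic ribosomal protein genes, 21 fell and 3 rose (-0.15), against 11 and 11 (-0.01). Over all 13140 tested genes, 3835 fell and 3723 rose, against 2553 and 5112 under total count scaling. On the TMM scale, falls among cytosolic ribosomal protein genes were thus about as common as among all genes, and rises were rarer.

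In mutant cells 16 of 20 stem and progenitor, 23 of 28 granulocyte and monocyte and 18 of 20 megakaryocyte genes rose. Each list had adjusted p = 0.169 by camera with an estimated correlation, which has little power with so few libraries. A sort that let in more of every other cell type need not raise their markers alike, since a rise also depends on the level in controls. The megakaryocyte median lay above the macrophage median by 1.88 (two-sided permutation of 20 and 11 genes between the lists, which share 0 genes, p = 0.00039, genes not being independent). Both lists were picked after the results were seen, as the highest and lowest medians among lists of non-erythroid cell types. The p does not allow for that choice, so a lower erythroid share stays open. Other medians were 1.83 for mast cell, basophil and eosinophil genes (5 tested) and 1.68 for lymphoid genes (4 tested). Such medians can lean upward, since genes scarce in controls were tested only if mutants expressed them. Mesenchymal genes had 1.68, endothelial genes 0.905 and hepatoblast genes 0.37. The sort for CD71 would remove cells without that marker, but not cells of other types that carry it. More granulocyte precursors would bring their granule transcripts. Mpo (0.73) and Prtn3 (1.31) did rise, but Elane fell (-0.87) and Ctsg had -0.53. The median of these 4 was 0.10 (SD 1.03), below the list median of 2.16. These 4 genes belong to that list and went both ways, so the comparison does not exclude more granulocyte precursors. More cells of one earlier progenitor stage, and a change within the progenitors of mutant genotype, stay open and untested, and these data may hold both.

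Embryonic globin transcripts rose in mutant cells. If one source supplied these transcripts in both groups and there was more of it, the 3 genes would rise by one factor; they differed by 0.60 (SE 0.07). Hepatoblast genes had a median of 0.37 (SD 0.32), which bears on free RNA from hepatoblasts only. Free RNA from primitive red cells need not raise hepatoblast genes, so that source stays open. Primitive red cells with another balance of globins, and expression in the mutant progenitors themselves, could each give the rise, and these were not tested.

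Xist rose in mutant pools. A larger share of female fetuses would lower Y-linked genes, whose median was 0.28 with all 4 above 0, also with each library left out, although single genes then missed the threshold. Such a change stays possible, since with few female fetuses among the controls it would shift Y-linked genes little. How much of the Xist rise it could give cannot be told from these genes. Reads of the antisense gene Tsix counted for Xist stay open too, since the use of strand is not given in the sources used here. A difference between the genotypes was not tested apart from the pools.

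Some values differed within a group, given here without an explanation. Of 41 called genes at least 16-fold higher in mutants with a mutant mean of at least 10 CPM, 28 had a higher CPM in control replicate 1 than in control replicate 2. An exact binomial test of the control counts, adjusted over the 41, passed for Csf2rb (adjusted p = 0.00023), Tec (0.007) and 1700025G04Rik (0.049). The rest did not pass, and that test covers counting error only. Csf2rb had 61 and 16 counts in these libraries, and Tec 43 and 12. Hist1h2af had 42 and 2086 counts in control replicates 1 and 2 and 35 and 1557 in mutant replicates 1 and 2.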
